A study of Mus musculus with 2 samples.

How the data were processed

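DNase-seq libraries of thymus tissue from 2 female B6CASTF1/J mice aged 36 days were used, 1 library per mouse. The labels name the mice as separate animals and number them as biological replicates 1 and 2, called mouse 1 and mouse 2 here. All coordinates are mm10 (GRCm38), per the labels.

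For each library the authors deposited 2 peak lists, a list of base runs with the FDR of the local cut rate, and a list of footprints. Per the text deposited with the files, peaks and cut rates were derived from that library's filtered alignments, and footprints from the cut rates and the alignments. The aligner, the peak caller, the footprint caller and their thresholds are not given in the sources used here. Peaks were listed per library, not on pooled reads. The signal column that the authors deposited with each peak is a depth-normalised height: in each library all values were whole multiples of 1 step (100% of values within 0.1 steps), 0.00638 in mouse 1 and 0.00504 in mouse 2. The name of the scale is not given in the sources used here; if it is reads per 1,000,000, the steps imply 157 and 198 M reads (M, 1,000,000). The p-value column of the cut-rate lists is an FDR that the authors computed and deposited only below 0.05. The deposited footprint lists carry 1 constant value, so only positions were used.

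The shorter and the longer peak list of a library differ in stringency. Peaks were compared with the merged runs of the cut-rate list described below, and peaks that touched no run were left out. Every other peak of the shorter list touched a run whose lowest FDR was at most 0.000957 in mouse 1 and 0.000992 in mouse 2. For the longer list these limits were 0.0497 and 0.0499. The base with the lowest FDR need not lie inside the peak. The shorter list was used throughout, a choice made after looking at the structure of the lists and before any overlap was computed. The longer list (93,107 and 117,361 peaks) was an alternative chosen after seeing the data. Touching runs of the cut-rate list were merged into regions, 175,838 in mouse 1 and 187,681 in mouse 2. These are the accessible regions, or regions of significant cutting.

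Genes, start sites and exons came from the GENCODE annotation of mouse genome GRCm38, and sequence from the GRCm38 reference. No interval lay past the end of its chromosome in that reference. A peak was counted at a promoter when it overlapped the 1,000 bp on either side of an annotated start site. The other peaks were assigned to exon, intron or intergenic sequence. Peaks were counted as shared when they overlapped by at least 1 bp. The random expectation came from 100 random placements of the intervals of the mouse named first, for peaks anywhere on the same chromosome outside assembly gaps, and for footprints within the accessible regions. Signals were compared on the log2 scale over pairs of peaks that overlap each other most.

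The gene lists (13 lists, 218 genes) and 30 consensus motifs were written before the data were examined. So were the tests, the alternatives and the rule for naming genes. All 218 genes matched a protein-coding gene on the autosomes or X. Peak density is the number of peaks in the gene body plus 10 kb on either side, per 10 kb. Windows of neighbouring genes can overlap, so a peak can count for several members of a list, and random lists were not matched on this. The median over a list of the mean of both mice was set against 10,000 random lists of protein-coding genes matched on window length in 10 groups. Promoter accessibility is the share of members with a promoter peak in both mice, against 10,000 random lists that were not matched. Both are two-sided permutation tests over genes, with Benjamini-Hochberg adjustment over 13 lists. They describe these libraries, and the spread between mice is given beside them. The named genes are the 2 highest and the 2 lowest members of each list by mean peak density, and the members of the T-lineage and effector lists without a promoter peak in either mouse. Also named are the 10 strongest shared peaks, the 5 strongest unshared peaks of each mouse, the 10 genes with most peaks and the 5 highest and 5 lowest motifs. A gene and a motif that entered the tests are not reported here.

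Motif matches on either strand were counted by their centre in footprint bases and in the other bases of accessible regions, 3.86 and 31.0 Mb in mouse 1 and 4.97 and 35.0 Mb in mouse 2. The log2 ratio of the match rates carries a jackknife SE over 20 chromosomes. A motif was called when the ratio exceeded 2 SE in both mice in the same direction. GC content was not matched between footprint and other bases. The motif written backwards served as a control of base composition.

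The methods were tested on simulated data. A planted peak sharing of 70.0% over 59,484 simulated intervals was recovered as 70.5%, and counts did not differ from those of bedtools. Of 200 lists of 16 genes with no planted effect, drawn from 21,728 genes, 3.5% passed 0.05 before adjustment in the density test. At a planted fold of 2, 56.5% passed, and at a planted fold of 3, 85.5%. In the promoter test 0.5% of lists without an effect passed, and 100% of lists with 15 of 16 planted open promoters. A planted motif of mean log2 ratio 5.38 was recovered at 5.43 and called in 20 of 20 simulated sequences. In 1 library, a motif without planted matches was called in 2 of 20 sequences when it had a mean of 42.3 matches in footprints, and in 5 of 20 when it had 3.3, so the SE is too small for rare motifs. Apart from planted matches, footprint and other bases had the same base composition in these sequences. Calls that arise from a difference in GC content were therefore not simulated.

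The number of reads per library is known only from the steps above, so intervals for counting error are not given. With 2 mice, SDs have 1 degree of freedom. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9 were used. Alternatives tried were a reciprocal overlap of 50%, the stronger 50% of each list, equal list lengths, promoter windows of 500 and 2,500 bp, protein-coding genes only, gene windows with 50 kb on either side, random lists also matched on local gene density, footprints moved by 50 bp as background, footprints over 1 kb from start sites, and each mouse left out. Parental alleles were not analysed here, since the lists used carry no allele counts.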

Results

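Chromatin accessibility was measured by DNase-seq in thymus tissue of 2 female mice aged 36 days. DNase-seq maps the places where the nuclease DNase I cuts nuclear DNA, which are the stretches not packed tightly around nucleosomes. The thymus is the organ in which T cells develop, and most of its cells are immature T cells (thymocytes). The mice were B6CASTF1/J animals, first-generation hybrids of the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ. Both libraries belong to 1 group, so no treatment or genotype was compared. The comparisons set the mice against each other, gene lists against random lists of genes, and motif matches in footprints against those in other accessible bases.

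Mouse 1 gave 59,484 peaks and mouse 2 gave 72,913, a mean of 66,198.5 ± 9,496 (SD, n = 2). The peaks covered 13.6 Mb in mouse 1 and 15 Mb in mouse 2, which was 0.499% and 0.550% of the genome. Their median widths were 220 and 200 bp. The deposited signal of every peak was a whole multiple of a fixed step per library, within a tolerance of 0.1 steps. If 1 step is 1 read per library and the scale is reads per 1,000,000, the steps correspond to 157 M reads in mouse 1 and 198 M in mouse 2 (M, 1,000,000). On that reading the weakest peak of either library held 10 reads, and the median peak held 192 reads in mouse 1 and 287 in mouse 2.

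Most accessible sites of the thymus were found in both mice, and the strong sites were shared almost completely. Of the mouse 1 peaks, 48,083 (80.8%) overlapped a mouse 2 peak by at least 1 bp. Of the mouse 2 peaks, 48,200 (66.1%) overlapped a mouse 1 peak. Peaks placed at random on the same chromosomes overlapped in 1.27% ± 0.047 (SD over 100 placements) and 1.04% ± 0.038 of cases, so the observed shares were 63.9-fold and 63.8-fold higher. The highest share in any placement was 1.37%.

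Sharing depended on peak strength. When the peaks of each mouse were divided by signal into 10 groups of equal size, the strongest group was shared in 99.7% of cases for mouse 1 and 99.0% for mouse 2. The weakest group was shared in 48.0% and 11.5%. Of all peaks in the weakest group, shared or not, 65.5% in mouse 1 and 26.0% in mouse 2 overlapped an entry of the other mouse's longer, more permissive peak list. Unshared at the thresholds of these lists were 24,713 peaks of mouse 2 and 11,401 of mouse 1.

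**Figure D1:**
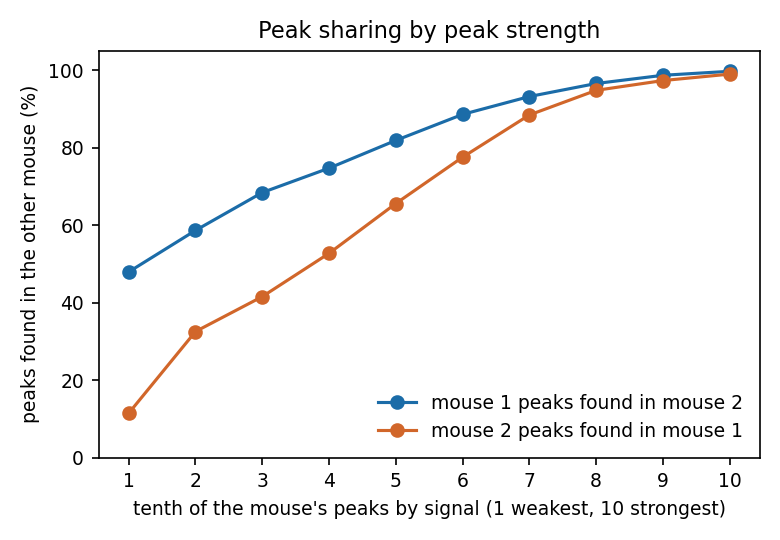
Share of peaks found in the other mouse (y axis, percent) for peaks divided by signal into 10 groups of equal size (x axis, weakest to strongest), with 1 line per mouse. The lines start at 48.0% for mouse 1 and 11.5% for mouse 2 and reach 99.7% and 99.0% in the strongest group.

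Of the 10 strongest shared peaks, 9 lay within 342 bp of an annotated start site. The highest mean signal was at chromosome 17, 6429981 to 6430180 (mm10), 31 bp from a start site of Dynlt1b, a dynein light chain gene with near-identical copies, so reads could have been shared among copies. Its signal was 66.3 in mouse 1 and 145 in mouse 2. A peak in an intron of Dnpep on chromosome 1 (75317481 to 75317940), 52 bp from its start site, had a signal of 62.7 ± 29.9 (SD, n = 2). Peaks near the start sites of Mplkip (61.1 ± 33.4), the nuclear receptor gene Esrra (54.4 ± 27.6), Gpbp1 (48.1 ± 20.7), Cactin (47.2 ± 16.2), the MYC antagonist gene Mxd1 (46.9 ± 18.5) and Papss1 (46.9 ± 25.7) followed. The remaining 2 of the 10 strongest shared peaks lay near the distal end of the X chromosome, at 169997961 to 169998260 within an intron of Mid1 (96.0 ± 52.3) and at 170009841 to 170010160 by Gm21887 (62.0 ± 10.4). All 10 signals were higher in mouse 2.

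Of the 10 strongest unshared peaks, 4 were neighbouring positions of the promoters of 2 genes. Mouse 1 had an unshared peak at Hbp1 on chromosome 12 (31950421 to 31950640, in its UTR, signal 25.1), and mouse 2 had one at 31950301 to 31950380 (signal 24.5). At the autophagy gene Uvrag on chromosome 7, mouse 1 had an unshared peak at 99141361 to 99141420 (signal 22.3) and mouse 2 at 99141081 to 99141360 (signal 32.7). The other unshared mouse 1 peaks among the strongest 5 were at Gpn3, Map3k11 and Ppp2r3d, and those of mouse 2 were at Sp1, Ubtd1 and an intron of Mid1 (X chromosome, 169991161 to 169991460, signal 81.7). All of these except the last touched a region of significant cutting in the other mouse.

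Across 46,907 pairs of shared peaks the log2 signals of the mice were correlated, with Pearson's r = 0.885 and Spearman's rho = 0.856. These are correlations across peaks, which are not independent replicates. The signal of mouse 2 was higher by a median log2 ratio of 0.75 (SD 0.76 across peaks), and 81.7% of pairs lay within 2-fold of that median. The ratio rose with the GC content of the peak. In the 5 equal groups of peaks from lowest to highest GC content, its median was 0.07, 0.30, 0.56, 0.94 and 1.42. Promoter peaks and the other peaks followed nearly the same course. Signals of single sites are therefore given per mouse or with their SD, and no site was called different between the mice, because each mouse is a single library.

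**Figure D2:**
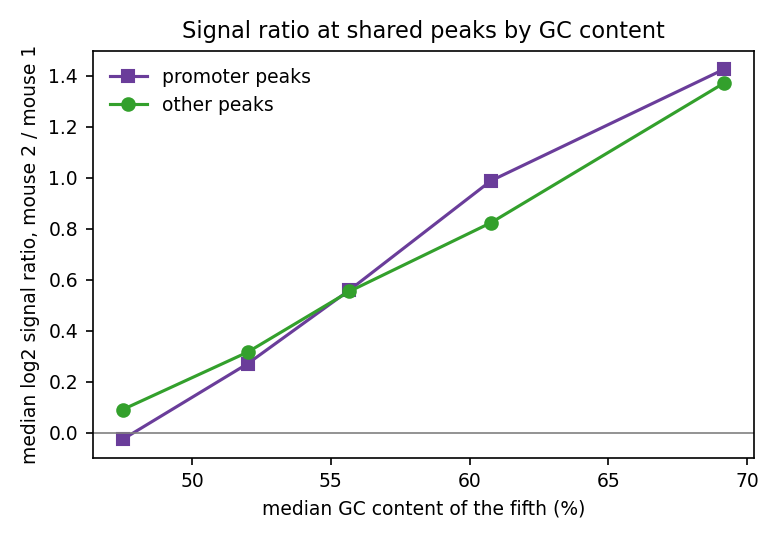
Median log2 ratio of the peak signal, mouse 2 over mouse 1 (y axis), in 5 equal groups of shared peaks by GC content (x axis, median GC percent of the group), for promoter peaks (squares) and all other shared peaks (circles). In the most GC-rich group the ratio was 1.43 for promoter peaks and 1.37 for the others, against -0.03 and 0.09 in the least GC-rich group.

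Accessible sites were concentrated at gene starts. Of the peaks, 43.7% ± 2.8 (SD, n = 2; 45.7% in mouse 1 and 41.8% in mouse 2) lay within 1,000 bp of an annotated transcription start site. These windows made up 5.88% of the total chromosome length, assembly gaps included, a 7.44-fold excess. Counting the gaps, and counting a peak when any part of it touched a window, both raise this ratio. Introns held 28.1% ± 0.93 of the peaks, intergenic sequence 23.5% ± 0.79 and exons away from promoters 4.65% ± 1.06. Promoter peaks were stronger, with a median signal of 2.21 ± 0.67 against 1.07 ± 0.09 in introns and 1.07 ± 0.11 between genes. Mouse 2 peaks in exons were found in mouse 1 in 48.1% of cases, against 74.1% of its promoter peaks. In mouse 1 the corresponding shares were 80.4% and 83.3%.

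Of 21,728 protein-coding genes, 12,368 (56.9%) had a promoter peak in mouse 1 and 13,723 (63.2%) in mouse 2. Both mice had one at 12,285 genes. A promoter peak was present in mouse 1 alone at 83 genes and in mouse 2 alone at 1,438 genes. Promoters opened in mouse 2 alone had a median GC content of 58.2%, against 46.3% for promoters closed in both mice. All open autosomal promoters had a median of 58.5% in either mouse. Promoters of mouse 2 alone were thus richer in GC than those closed in both mice, and close to open promoters in general. The X chromosome had the lowest peak density apart from Y, 9.88 ± 1.17 peaks per Mb (SD, n = 2), against 19.4 ± 1.7 on chromosome 3, the sparsest autosome, and 46.7 ± 8.4 on chromosome 11, the densest.

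The genes that define developing T cells were surrounded by accessible sites. Members of the T-cell receptor, CD3 and co-receptor list had a median of 3.43 peaks per 10 kb of gene window (2.09 in mouse 1 and 4.16 in mouse 2), 7.08-fold the 0.485 of random gene lists. Thymocyte transcription factors had 2.07 peaks per 10 kb (1.85 and 1.96 in the single mice), 5.47-fold the random value. Genes of V(D)J recombination and the pre-T-cell receptor stage had 1.69 (1.48 and 1.79), 3.52-fold. Housekeeping genes had 1.88 (1.80 in either mouse), 3.25-fold. In a permutation test against 10,000 random lists matched on window length, each of these 4 lists had an adjusted p of 0.00065 (two-sided, Benjamini-Hochberg over 13 lists). The unadjusted p was 0.0001 for the first pair, the smallest that the random lists can give, and 0.0002 for the other pair.

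Single genes spanned a wide range. Tcf7, which encodes the TCF-1 factor needed for T-cell specification (chromosome 11, 52252371 to 52283014), had 48 peaks in mouse 1 and 70 in mouse 2 in its gene body and 10 kb on either side, or 11.6 ± 3.1 per 10 kb (SD, n = 2), the highest of its list. Cd8b1, a chain of the CD8 co-receptor, had 23 and 47 peaks, and the adhesion receptor gene Cd2 had 23 and 24. The lowest densities among the transcription factors were at the long genes Tcf12 (9 and 6 peaks) and Tox (14 and 15 peaks). Among the receptor genes the lowest were at Themis (6 and 7 peaks) and Trat1 (0 and 2 peaks). In the recombination list the chemokine receptor gene Ccr7 had 7 and 23 peaks and the Notch target Hes1 had 9 and 7, while the interleukin-7 receptor gene Il7r had 1 in each mouse and Arpp21 had 10 and 18. Among the housekeeping genes Eef2 had 13 and 24 peaks and Rpl13a 16 and 10, and the lowest densities were at Sdha (3 in each mouse) and Hprt (3 and 5).

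**Figure D3:**
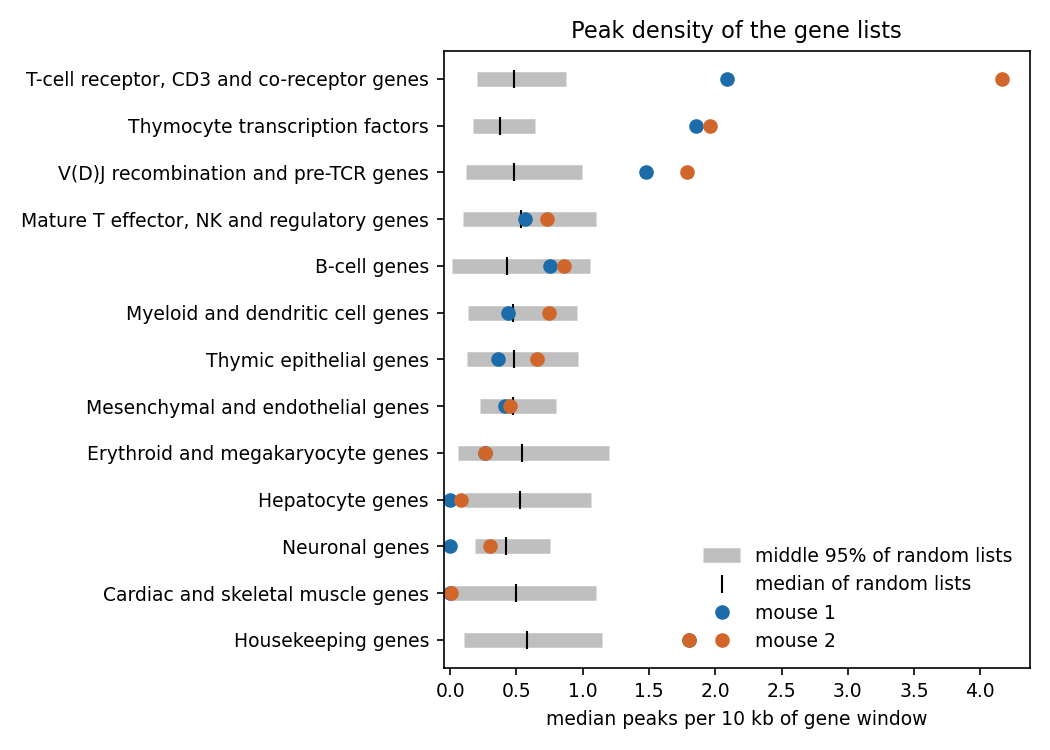
Median number of peaks per 10 kb of gene window (x axis) for each of the 13 gene lists (y axis), with 1 point per mouse, a grey bar for the middle 95% of 10,000 random lists and a tick for their median. The T-cell receptor list stands at 2.09 and 4.16 in the single mice, against a random median of 0.485.

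The 9 other lists, of mature effector cells, other cell types of the thymus and absent tissues, did not pass the threshold in peak density. Mature T effector, NK and regulatory genes had a median of 0.706 peaks per 10 kb (adjusted p = 0.555, permutation test), B-cell genes 0.771 (adjusted p = 0.276), myeloid and dendritic cell genes 0.655 (0.436 in mouse 1 and 0.744 in mouse 2; adjusted p = 0.470), and thymic epithelial genes 0.536 (0.358 and 0.653; adjusted p = 0.794). Mesenchymal and endothelial genes had 0.432 (adjusted p = 0.794) and erythroid and megakaryocyte genes 0.265 (adjusted p = 0.450), by the same permutation test. The tissues absent from a thymus had values below their random medians that did not pass the threshold: hepatocyte genes 0.0800, neuronal genes 0.151 and cardiac and skeletal muscle genes 0.00436, each with an adjusted p of 0.133 in the permutation test. Without mouse 2 all 3 medians were 0, and the neuronal list passed with an adjusted p of 0.0289 in that test. With 50 kb on either side the muscle median was 0.397 and the hepatocyte median 0.207, and with the longer peak list the muscle, hepatocyte and neuronal medians were 0.558, 0.244 and 0.431.

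Within these lists, members with many peaks stood beside members with none. The effector genes Gzmb, Ifng and Ncr1 had no peak in either mouse, whereas Nkg7 and Prf1 each had 5 in mouse 1 and 2 in mouse 2. Of the B-cell genes, Cd79a had 9 and 7 peaks and Igll1 5 and 3, while Ms4a1 (CD20) had none and Pax5 had 2 and 3. The C/EBP factor genes Cebpb (8 and 9 peaks) and Cebpa (1 and 6) led the myeloid list, and the macrophage genes Adgre1 and C1qa had none. Cldn4 had 15 and 4 peaks and the thymic serine protease gene Prss16 had 4 and 6 in the epithelial list, where Cldn3 and Fezf2 had none. Plvap (4 and 7) and Pecam1 (8 and 16), both endothelial genes, led the stromal list, in which Col3a1 and Dcn had none. Klf1 (6 and 5) and Gp1ba (5 in each mouse) led the erythroid and megakaryocyte list, in which Alas2 and Gp9 had none. In the lists of absent tissues the highest densities were at Tat (2 and 3 peaks) and Fgb (1 and 2), Slc17a7 (6 and 9) and Camk2a (5 and 10), and Tnni3 (2 and 5) and Ckm (5 and 4). No peak was found at the hepatocyte genes Ahsg and Cps1, the neuronal genes Nefl and Syt1, or the muscle genes Acta1 and Actc1.

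By promoter accessibility 7 of the 13 lists passed the threshold, 4 as higher and 3 as lower. A promoter peak was present in both mice at 19 of 20 T-cell receptor genes (adjusted p = 0.00234), 19 of 20 thymocyte transcription factors (adjusted p = 0.0013), 12 of 12 recombination genes (adjusted p = 0.0145) and 18 of 18 housekeeping genes (adjusted p = 0.000433), all higher than in random lists by a two-sided permutation test. The random median was between 55.0% and 58.3% for these lists. Promoter peaks were rarer than in random lists at hepatocyte genes, with 1 of 16 (adjusted p = 0.000433), muscle genes, with 1 of 16 (adjusted p = 0.000433), and neuronal genes, with 4 of 16 (adjusted p = 0.0436, permutation test). An unadjusted p of 0.0001, the smallest possible, underlay the housekeeping, hepatocyte and muscle values. Of the 16 muscle promoters, 1 was open in mouse 1 and 4 were open in mouse 2. The neuronal value came from mouse 1: 4 neuronal promoters were open there and 12 in mouse 2, where the share of 75% was above the random median, with an adjusted p of 0.477 in the permutation test. The neuronal share did not pass with a promoter window of 2,500 bp (37.5%) or with the longer peak list (62.5%). The recombination genes did not pass in mouse 2 alone (12 of 12, adjusted p = 0.0708, permutation test) or for the stronger 50% of peaks (83.3%, adjusted p = 0.051).

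The remaining 6 lists did not pass the threshold. A promoter peak in both mice was present at 8 of 16 effector genes (adjusted p = 0.806, permutation test), 7 of 15 B-cell genes (0.526), 8 of 19 myeloid genes (0.311), 9 of 20 epithelial genes (0.548), 6 of 16 stromal genes (0.294) and 4 of 14 erythroid and megakaryocyte genes (0.0889). Among the T-lineage and effector lists, Trat1, Klrb1c, Il2ra, Il4, Gzmb, Ifng and Ncr1 had no promoter peak in either mouse. Il2ra, the interleukin-2 receptor alpha gene used to stage early thymocytes, had 9 peaks elsewhere in its window in each mouse, and Klrb1c had 2 and 6. Of the housekeeping genes named by density, Rpl13a had a promoter signal of 18.1 in mouse 1 and 28.7 in mouse 2, and the elongation factor gene Eef2 had 10.1 and 27.8. Ckm was the muscle gene with a promoter peak in both mice (5.74 and 17.3).

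Counted without regard to length, the most peaks lay in 10 gene windows, some of which overlap. Gm20388 on chromosome 8 had 355 and 492 peaks, in a window of 4,455 kb that spans many other genes. Fgfr2 on chromosome 7 had 94 and 118 in a window of 2,981 kb. Its density of 0.356 peaks per 10 kb was below the median of 0.468 over all protein-coding genes. Gse1 had 73 and 102 peaks and lies within the Gm20388 window. Tcf7 came next, with a mean of 59 ± 15.6 peaks, in a window of only 50.6 kb. Gm20696 (54 and 62) overlaps Foxp1 (45 and 52), a forkhead factor of lymphocytes. Sept9 had 40 and 61 peaks, the retinoic acid receptor gene Rara 40 and 59, and the cyclin D3 gene Ccnd3, which drives thymocyte proliferation, 32 and 64. Jakmip1 had 23 and 76, the largest ratio between the mice in this group.

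Footprints are short protected stretches inside accessible regions, where a bound protein can block cutting. There were 294,945 in mouse 1 and 347,542 in mouse 2, with median lengths of 10 and 11 bp. At least 1 footprint was present in 87.0% of mouse 1 peaks and 89.7% of mouse 2 peaks, and 99.5% and 99.7% of footprints touched a region of significant cutting. Footprints of mouse 1 were found in mouse 2 in 55.6% of cases, against 20.9% ± 0.07 (SD over random placements within the accessible regions). In the other direction 45.2% were found, against 17.2% ± 0.06. Footprints were thus shared 2.66-fold and 2.62-fold more often than under uniform placement in the accessible regions. Their share was smaller than that of whole peaks. In mouse 1 and mouse 2, 64.84% and 63.04% of footprints touched a peak. Peaks covered 13.59 and 14.98 Mb, against 34.9 and 39.9 Mb of accessible regions. The placements did not keep this concentration in peaks, which can itself raise sharing. The folds therefore do not separate shared positions inside a site from shared sites.

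Footprints were most enriched in matches to the motifs of RFX, NRF1 and CTCF. Of 30 motifs fixed before the data were examined, 16 were more frequent in footprint bases than in other accessible bases in both mice by over 2 jackknife SE, 6 were less frequent, and 8 were neither. The 5 highest log2 ratios were those of RFX (6.58 ± 1.08, SD, n = 2), NRF1 (6.21 ± 0.30), CTCF (5.28 ± 0.92), the CRE site of CREB and ATF factors (4.4 ± 0.15) and SP/KLF (3.67 ± 0.01). The RFX value rests on 42 and 46 matches in footprints and on only 6 and 2 in other accessible bases, and in mouse 1 NRF1 (6.43) was above RFX (5.81). CTCF, the factor that insulates chromosome domains, had 3,583 and 5,205 matches in footprints, 24.9-fold and 60.9-fold over other accessible bases. REST (3.51 ± 1.26, from 29 and 114 matches), EGR (3.40 ± 0.19), ZNF143 (3.33 ± 0.57), YY1 (3.01 ± 0.13), CEBP (1.34 ± 0.02), ETS (1.12 ± 0.19) and the E-box CACGTG (0.94 ± 0.19) were also higher. REST matches were 6.13-fold enriched in mouse 1 and 21.1-fold in mouse 2. The YY1 ratio fell to 1.60 with footprints moved by 50 bp as background. More than 1 kb from start sites several ratios were lower, among them those of NRF1 (4.47), CRE (3.32), SP/KLF (2.78), ZNF143 (2.23) and ETS (0.68).

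The TCF/LEF site, bound by TCF-1 and LEF-1, had a log2 ratio of 0.81 ± 0.30 and the RUNX site 0.36 ± 0.19. NFY (0.61) and the NEUROD-type E-box (0.58) lay between them. RUNX was not called with footprints moved by 50 bp as background (0.23), nor CEBP away from start sites (1.01), and NFY turned to -0.18 there. The 5 lowest ratios were at the p53 and p63 site (-1.70 ± 0.35), GATA (-1.04 ± 0.13), AP-1 (-0.88 ± 0.12), OCT (-0.80 ± 0.13) and NFAT (-0.76 ± 0.08), and MYB (-0.32 ± 0.04) was the sixth that was lower. The E-box CAGCTG, bound by the E-proteins of thymocytes, was not called: its ratio was 0.27 in mouse 1 and -0.06 in mouse 2, over 2 SE in opposite directions, and it was called as higher more than 1 kb from start sites (0.47). PU.1 (0.07), IRF (0.04), NF-kB (-0.18), HNF4 (-0.28) and MEF2 (-0.50) were not called either, and HNF1 had 0 and 1 matches in footprints. In mouse 2 alone NF-kB (-0.34) and MEF2 (-0.61) were lower. Footprint bases were richer in GC than the other accessible bases, 64.4% against 53.7% in mouse 1 and 64.8% against 55.4% in mouse 2. Of the 15 raised motifs that differ from their own backwards spelling, 13 exceeded it, and RFX and REST had no value for it. SP/KLF reads the same backwards, so it had no such control. The backwards spellings of CRE and of the E-box CACGTG lack the CG step of the motif, so they do not control for it. Of the 6 lower motifs, NFAT, OCT and GATA were less low than their backwards spelling, and MYB, AP-1 and the p53 and p63 site differed from theirs by -0.12 to -0.19.

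**Figure D4:**
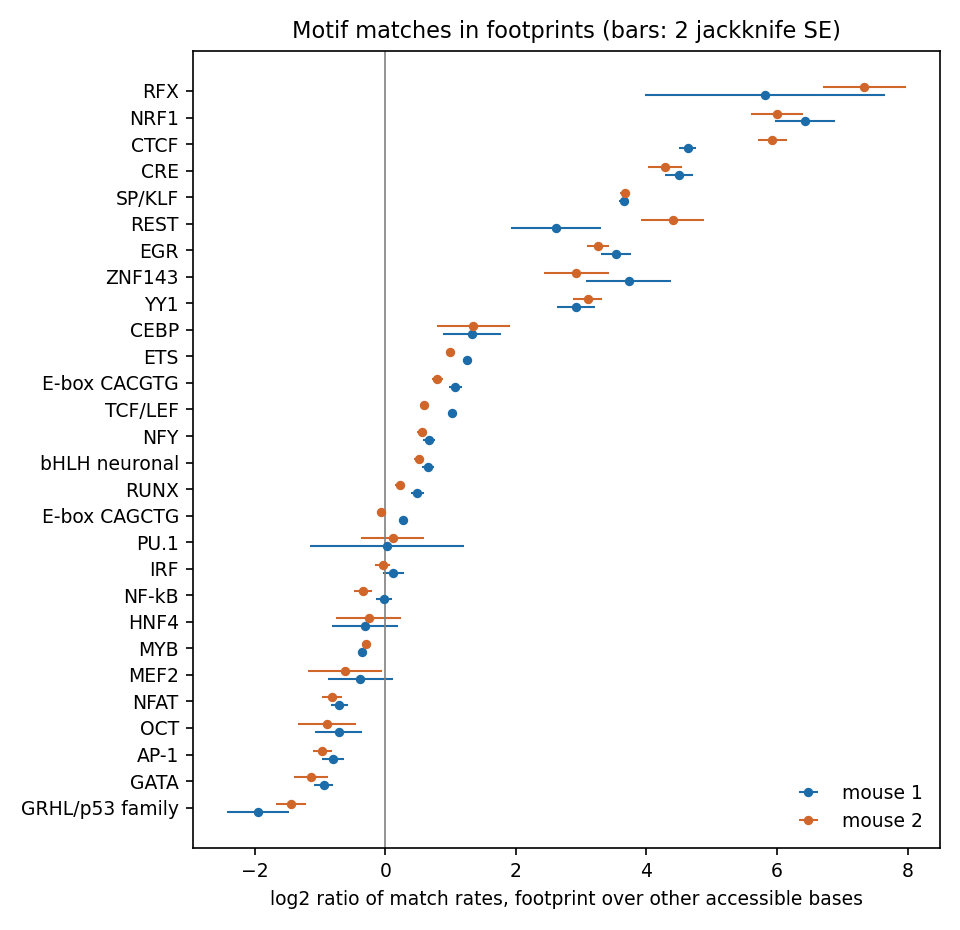
Log2 ratio of motif match rates in footprint bases over other accessible bases (x axis) for the motifs reported here (y axis), with 1 point per mouse and bars of 2 jackknife SE over 20 chromosomes. The values run from 6.58 for RFX to -1.70 for the p53 and p63 site, as means of both mice.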

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

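Peaks were listed on chromosome Y although both mice are female per the labels. Mouse 1 had 31 peaks there and mouse 2 had 36, where a count of 0 would allow 3. That limit covers counting error only, and the number to be found from misplaced or pseudoautosomal reads was not measured. Of these, 10 in mouse 1 and 18 in mouse 2 lay in the last 1.1 Mb of the chromosome, between 90718601 and 90744820 in mouse 1 and between 90717658 and 90744820 in mouse 2. The highest signal there was 9.96 and 14.9. Elsewhere on Y the highest signal was 0.657 and 1.01, and the median signal was 0.179 and 0.144. No explanation was tested for these peaks. The last 1.1 Mb of the X chromosome held 61 peaks in mouse 1 and 43 in mouse 2, with highest signals of 61.3 and 137, and 2 of the 10 strongest shared peaks of the genome lay there. With 1 group of 2 mice, neither a mouse far from its group nor a difference between groups could be looked for.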

How the results depend on the processing

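The longer peak list was an alternative chosen after seeing the data, and all other alternatives were fixed before the data were examined. Of 314 alternative values, 276 kept their side of the threshold and the direction of any call, or moved by less than the spread or tolerance set for them. Some of these were values without a call that changed sign, such as HNF4, from -0.28 to 0.36 with footprints moved by 50 bp as background. The cause of the other shifts was not tested, except where the alternative itself is stricter or wider. Shares of peaks depended on what counts as shared. For mouse 1 and mouse 2 peaks respectively they were 67.6% and 55.1% with a reciprocal overlap of 50%, 95.3% and 91.4% for the stronger peaks against all peaks, 76.2% and 76.3% with equal numbers of peaks, and 75.4% and 60.03% with the longer list. Footprint sharing fell to 38.1% and 32.3% with a reciprocal overlap of 50%. Equal numbers of footprints by score were not run, because the score is constant. The promoter share was 36.2% with a window of 500 bp, 53.9% with 2,500 bp, 55.6% for the stronger peaks, 39.1% with protein-coding genes only and 36.4% with the longer list. It ranged from 41.8% to 45.7% with either mouse left out. The 4 higher lists of the density test kept their call under every alternative run. The neuronal density ranged from 0 to 0.302 with either mouse left out, and passed the threshold (lower) without mouse 2. In the promoter test the neuronal share was 37.5% with a window of 2,500 bp and 62.5% with the longer list, neither past the threshold. With either mouse left out it ranged from 25% to 75%, and its direction turned without mouse 1. The recombination genes missed the threshold for the stronger peaks (83.3%, adjusted p = 0.051, permutation test). With either mouse left out their share was 100%, and the threshold was missed without mouse 1. Mesenchymal and endothelial genes (6.25%) and erythroid and megakaryocyte genes (14.3%) passed as lower for the stronger peaks. The erythroid share of 28.6% passed with the longer list, and without mouse 1. Backwards motifs gave 3 higher and 14 lower calls, against 16 and 6 for the motifs themselves. With either mouse left out, 16 to 17 motifs were higher and 6 to 10 lower, 10 of them without mouse 1. NFY turned to a log2 ratio of -0.18 more than 1 kb from start sites, and the E-box CAGCTG ranged from -0.058 (without mouse 1, lower) to 0.27 (without mouse 2, higher), each past 2 SE. NF-kB (-0.34) and MEF2 (-0.61) were called as lower without mouse 1. No paired analysis was possible because there is 1 group. The weakest 10% of mouse 2 peaks were found in mouse 1 in 11.5% of cases, and whether depth sets this was not tested.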

Other observations

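Gene families outside the fixed lists were looked at after the data had been seen, so their values are descriptions without a test. Of the tests further on, those of the signal ratio by GC content, the allowance for choosing the neuronal list, the matching of the escape genes on GC content and the gap in distal peaks of the T-cell receptor list were chosen after the result was seen. Of 1,134 olfactory receptor genes, 7 had a promoter peak in both mice and 1,121 in neither. Of 330 vomeronasal receptor genes, 1 had one. Cytochrome P450 genes of drug and steroid metabolism had 12 of 81 and keratin genes 3 of 53. At the other end stood proteasome subunit genes (38 of 40), genes with symbols starting in Rpl or Rps and a digit (88 of 98) and histone genes (58 of 67). The Rpl and Rps symbols include those of cytosolic ribosomal proteins. All families were picked by gene symbol, so the counts can include genes of another kind that share the symbol's start. Interleukin receptor genes had 27 of 41 open promoters and MHC class II genes 6 of 9. Hox genes, which pattern the body axis, had 10 of 39. Collagen genes had 10 of 45 in mouse 1 and 20 of 45 in mouse 2.

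The antigen receptor loci differed by receptor. Within 10 kb of the constant gene Trac of the T-cell receptor alpha chain there were 10 peaks in mouse 1 and 22 in mouse 2, with a highest signal of 28 and 27.8. The beta chain constant genes Trbc1 (10 and 11 peaks) and Trbc2 (7 and 12) were also dense, in windows that overlap, and the delta chain gene Trdc had 8 and 2. Among the gamma chain genes, Tcrg-C4 had 3 and 4 peaks, whereas Tcrg-C1, Tcrg-C2 and Tcrg-C3 had none. Of the immunoglobulin constant genes, Ighm had 3 and 8 peaks and Ighd, whose window overlaps, 2 and 5, Igkc had 0 and 1, and the lambda chain constant genes had none. Away from start sites, the windows of the T-cell receptor, CD3 and co-receptor genes held 111 peaks in mouse 1 and 211 in mouse 2. A peak in overlapping windows was counted for each gene. The gap of 100 between the mice was above nearly all of 10,000 random lists matched on window length (percentile 99.9). The random lists were not matched on their number of peaks or on overlap between windows. Of the other lists, thymocyte transcription factors lay above the central 95% of random lists (244 and 301 peaks, percentile 99.4) and thymic epithelial genes below it (23 and 19 peaks, percentile 1.65). A list with many peaks can have a wide gap for that reason alone. High percentiles alone therefore do not show a gain beyond what the number of peaks gives. Between these 2 lists, however, the number of peaks does not order the gaps. The transcription factor list had more peaks than the T-cell receptor list in both mice and a smaller gap, 57 against 100. With each peak counted once, the T-cell receptor list had 196 mouse 2 peaks away from start sites. Of these, 111 were absent from mouse 1, and 36.9% of those lay in a mouse 1 region of significant cutting.

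The median log2 ratio of mouse 2 over mouse 1 rose by 1.35 (jackknife SE 0.018) between the 5 equal groups of lowest and highest GC content. A uniform difference in depth would leave this at 0 if it did not affect which peaks are shared. Peak strength was not matched between the groups. Over all peaks, mouse 2 exceeded mouse 1 by 1.18-fold in median signal and 1.79-fold at the 90th percentile, so strength is not separated from GC content here. Promoter peaks had a higher ratio than other peaks by 0.59 before matching and by 0.0044 (SE 0.010) at matched GC content, which argues against promoters being more accessible in mouse 2 as such. A candidate explanation that these values leave open is a GC bias that differs between the libraries. Peaks of mouse 1 alone had a median GC content of 50.3%, against 56% for its shared peaks. Peaks of mouse 2 alone had 56.2%, against 56.5% for its shared peaks, and were thus richer in GC than peaks of mouse 1 alone. A GC content of 60% or more was reached by 31.0% of the peaks of mouse 2 alone and by 14.1% of those of mouse 1 alone. Shared and unshared peaks were not matched on strength.

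More neuronal promoters were open in mouse 2 than in mouse 1, a pattern seen before these tests were chosen: of 12 members closed in mouse 1, 8 were open in mouse 2 (Camk2a, Gad1, Gad2, Nefm, Slc17a6, Slc17a7, Snap25 and Stmn2), with promoter signals from 0.207 (Stmn2) to 1.42 (Camk2a), below the median mouse 2 peak (1.45). That share of 66.7% stood at percentile 99.95 of random lists of genes closed in mouse 1 with the same promoter GC content, whose median was 25%, and at percentile 99.8 when matched on the most GC-rich 200 bp near a start site. Among random sets of the 9 lists with at least 3 members closed in mouse 1, 0.36% and 1.38% held a list as high. Genes of equal GC content therefore rarely gave such a share. The random genes were not matched on accessibility below the threshold in mouse 1. A GC bias that lifted promoters from just below the threshold can therefore not be told apart. Neuronal cells in the mouse 2 tissue cannot be told apart from no such cells: the neuronal windows held 9 more distal peaks in mouse 2, near the median of 8 in random lists and inside their central 95% (-4 to 32). Weak peaks near the threshold stay open as well, since 62.5% of the neuronal promoters were open in both mice with the longer peak list, against 25% with the shorter one.

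Open promoters of X-linked genes had a lower signal than autosomal ones, 3.17 against 5.04 in mouse 1 and 5.21 against 10.7 in mouse 2. The gap in log2 was -0.67 and -1.04, and at matched promoter GC content it was -0.61 (bootstrap SE 0.087) and -0.69 (SE 0.14), a mean of -0.65, which argues against GC content as the whole cause. A candidate explanation is that 1 X chromosome is inactive in each cell of a female, and Xist, the RNA gene that silences it, had 2 promoter peaks in each mouse (highest signal 1.24 and 2.35). The escape genes Kdm6a, Kdm5c, Ddx3x, Eif2s3x and Pbdc1, which are known to stay active on that copy, had a median promoter signal of 7.16 and 19.0, at percentiles 97.8 and 99.8 of random X-linked lists, outside the central 95% in both mice, as that explanation predicts. Matched on GC content they stood at 97.4 and 99.7, the first just inside the central 95%, so X inactivation stays open.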
